A study of Rattus norvegicus with 10 samples.

How the data were processed

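Islet RNA of 10 samples, 5 that received the Nkx6.1 adenovirus and 5 that received the bGAL adenovirus, was profiled on two-colour Operon rat 27K oligonucleotide arrays. Per the labels, islet pools of about 200 islets per condition were treated with 5E9 virus particles per ml for 18 h and cultured for a further 60 h, and 500 ng of total RNA was amplified and labelled with Cy5. It was hybridised with one Cy3-labelled rat reference RNA on every array, with no dye swap, per the labels. Groups and replicate numbers were taken from the sample titles. The methods of background correction, dye normalisation and filtering are not given in the sources used here.

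The deposited values are log2 ratios, and their scale, centring and direction were found from the values themselves. Each of the 17744 probes with 10 values had a median of 0 over the 10 samples (tolerance 0.001), so each probe was centred on its own median and no level of a gene can be read. The median of each array lay between −0.0028 and 0. The base of 2 was inferred from 101 values at a distance of 13.29 above a probe's floor and 4 at that distance below it, which is the base 2 logarithm of 10000. Between pairs of arrays, Pearson's r was −0.13 to 0.48 and Spearman's rho −0.49 to 0.51 across probes, which are not independent. The planned check of the ratio's direction, by the rank of hormone genes within an array, could not be made on centred values. In its place, chosen after the values were seen, probes with the same value in 3 or more samples (to 4 decimals) were used. Those values were taken as a floor in both channels, hence a ratio of 1, and there were 7209 such probes, 40.6% of those with 10 values. For each of these probes the mean was taken over array set 2, defined below. That set held bGAL replicate 4 and Nkx6.1 replicates 2 to 5, so mostly Nkx6.1 samples. The mean lay above the floor for 6 of 6 glucose sensing probes and 9 of 10 neuronal probes, and for 0 of 6 DNA replication probes and 2 of 11 mitosis probes. Other lists were less clear, with 4 of 6 islet transcription factor, 10 of 13 acinar, 3 of 6 duct, 4 of 7 endothelial, 4 of 6 interferon, 3 of 8 stellate, 3 of 7 p53, 2 of 9 inflammation and 2 of 5 G1/S probes, and 3974 of all 7209 lay above the floor. On this basis the ratio is likely islet over reference, and all signs rest on it.

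Samples with over 20% of probes without a value were called array set 1 and the others array set 2, a technical split found after the values were seen. Of 26984 probes, 22 were control probes and were left out. A single gene symbol was given for 15807 of the rest in the platform annotation used here, several for 0 and none for 11155. Among those with a symbol, 12034 were current in the GRCr8 RefSeq gene table, 3713 were updated through a unique synonym and 60 were kept. By symbol, Pdx1, Ccnb1 and Ccne1 were not analysed here, and Cdkn1a and Mafa had too few values to be tested. Coordinates were not used here. No column of sample values was left unused.

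Differences were computed as Nkx6.1 minus bGAL on the deposited log2 values with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, for probes and for genes with at least 3 values per group. Values of several probes for a gene were averaged. P-values were adjusted by Benjamini-Hochberg over all probes or all genes, with a threshold of 0.05. Gene lists, each with at least 5 measured members, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. These tests used the 9617 genes with 10 values, so filters on missing values do not change them. The 21 lists covered G1/S regulators, DNA replication, G2/M and mitosis, kinase inhibitors, islet hormones, islet transcription factors, glucose sensing and secretion, acinar, duct, endothelial, stellate and fibroblast, and macrophage and leukocyte markers, interferon and antiviral genes, inflammation, ER stress, p53 and apoptosis, immediate early genes, glycolysis and hypoxia, oxidative phosphorylation, cholesterol and fatty acid synthesis, and neuronal genes. No gene stood in more than 1 list. Single values were compared by an exact two-sided permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

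The tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls past the threshold, all of them where fewer passed, filled to 6 with the smallest p. It added the 4 members with the smallest p of each list that was shifted or concerned the cell cycle or islet function, and 23 genes fixed by name. Tacc3 was named after its values were seen. On simulated data of 9974 genes with the real spread (median residual SD 0.55), 8 of 100 genes changed by 1 on the log2 scale and 52 of 100 changed by 2 were called, with 5 false calls and 0 of the wrong sign. The raised list was called, and 0 of the other lists were. Genes were drawn independently and without array sets, so this does not show how often the list tests err on real data. The alternatives were the replicate number as a block, median centring, quantile normalisation, other filters on missing values, trend and robust eBayes, array weights, the most variable probe per gene, other set tests, thresholds and ordinary statistics, and each sample left out. Chosen after the values were seen were a term for the array set and leaving out floored probes or probes with a value above 8 in size. The median shift of all genes was −0.052 as deposited, −0.051 after median centring and −0.0090 after quantile normalisation.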

Results

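Gene expression was measured in rat pancreatic islets, the clusters of hormone-secreting cells of the pancreas, after transduction with an adenovirus that carried either hamster Nkx6.1, a homeodomain transcription factor of insulin-producing β cells, or bacterial β-galactosidase as the control (bGAL). Each group held 5 samples from independent islet isolations of male Sprague-Dawley rats, 10 samples in all. The islets were exposed to virus for 18 h and cultured for a further 60 h at 8 mM glucose. Each sample was hybridised in Cy5 against a common rat reference RNA in Cy3 on a two-colour oligonucleotide array with 26962 probes besides controls, and the number of arrays limits the precision. A value is the log2 ratio to the reference, centred on the probe's median over the 10 samples. The sign was taken as islet over reference, which is likely but not stated. The arrays fell into 2 sets. In array set 1, which held bGAL replicates 1, 2, 3 and 5 and Nkx6.1 replicate 1, between 27.3% and 32.5% of the probes had no value. In array set 2, which held bGAL replicate 4 and Nkx6.1 replicates 2 to 5, between 0.816% and 9.13% had none. The array set was therefore largely aligned with the group, and values within each set are given for the lists that were shifted or concerned the cell cycle or islet function, and for genes whose sign turned. Nkx6.1 replicate 2 also had the widest spread of values, with an interquartile range of 1.09 on the log2 scale against 0.35 to 0.58 in the other samples.

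**Figure D1:**
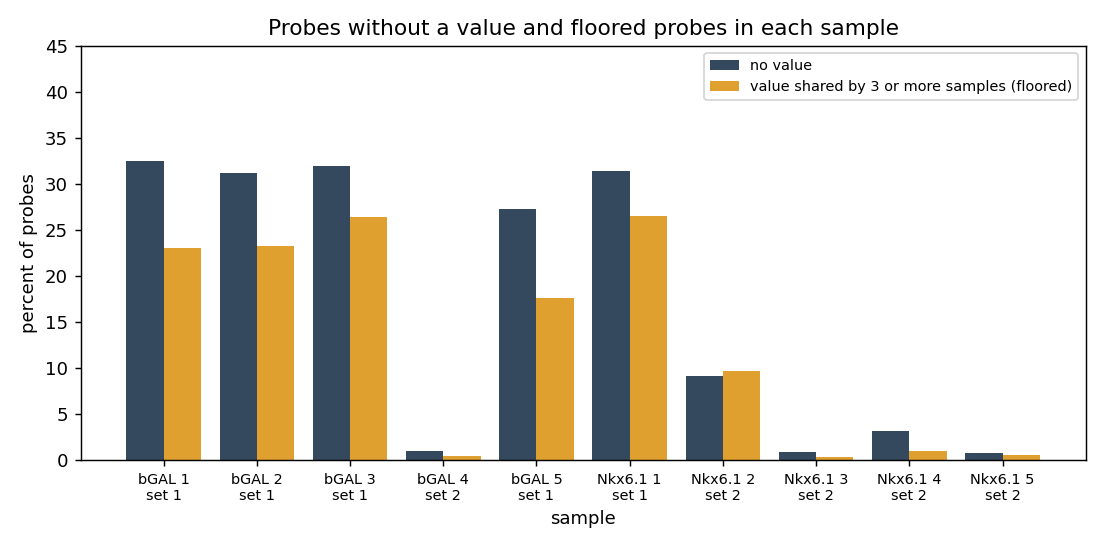
Bars give, for each of the 10 samples on the horizontal axis, the percent of probes without a value (dark) and the percent of probes whose value was shared by 3 or more samples (yellow, treated as floored). The 5 samples of array set 1 had 27.3% to 32.5% of probes without a value, and the 5 samples of array set 2 had 0.816% to 9.13%.

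The first comparison asked which transcripts differed between islets that received the Nkx6.1 virus and islets that received the control virus, in a study whose title concerns β-cell proliferation with retained function. Genes of mitosis were prominent among those that rose. Cdk1, the kinase that drives entry into mitosis, was 6.17-fold higher with the Nkx6.1 virus (centred log2 ratio 1.25 ± 0.27 against −1.37 ± 0.36, SD, n = 5 per group, limma adjusted p = 0.0018). Cdkn3, a phosphatase that acts on cyclin-dependent kinases, was 4.04-fold higher (0.99 ± 0.23 against −1.03 ± 0.16, limma adjusted p = 0.0018). Hmmr and Aurka, which encode proteins of the mitotic spindle, were 4.19-fold and 3.45-fold higher, and the microtubule regulator Stmn1 was 2.94-fold higher. The kinase gene Melk rose 2.88-fold and the spindle checkpoint gene Mad2l1 rose 2.34-fold. Of the 11 genes that rose, these 7 were members of the list of 42 measured G2/M and mitosis genes, where 0.046 were expected by chance (Fisher's exact test, two-sided, p = 4.5e-15). That test treats genes as independent, which genes measured on the same samples are not. Its p therefore does not measure chance among the samples. The other 4 genes that rose were Ckap2 (3.15-fold) and Ska1 (2.88-fold), which both encode microtubule-associated proteins of dividing cells, Dusp1 (2.27-fold), a phosphatase of MAP kinases induced as an early response gene, and a gene of the Ly6 family, named Ly6b in the deposited annotation and updated here to Ly6i (4.14-fold).

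Only 4 genes fell. Rbp4, the plasma carrier of retinol, fell by 2.92 on the log2 scale (−1.88 ± 0.72 against 1.05 ± 0.23, SD, n = 5 per group, limma adjusted p = 0.013), a 7.59-fold lower level with the Nkx6.1 virus. Calcb, which encodes a calcitonin gene-related peptide, was 6.63-fold lower, Lrrn3, a leucine-rich repeat membrane protein gene, was 6.19-fold lower, and Hhex, a homeobox transcription factor known from somatostatin-producing δ cells, was 3.53-fold lower. In every one of the 15 genes that changed, all 5 Nkx6.1 samples lay beyond all 5 bGAL samples. This is also the outcome with the smallest p that an exact two-sided permutation test of 5 against 5 can give, 0.0079. Of the falls that did not pass, Brinp1 had a log2 difference of −2.42 (−3.14 and −0.80 within array sets 1 and 2) and Tgm4 one of −11.7, each with limma adjusted p = 0.098. Tgm4 stood between 2.44 and 14.0 in the bGAL samples, with 3 of them at 8.71 or above, and between −3.89 and −2.44 in the Nkx6.1 samples.

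**Figure D2:**
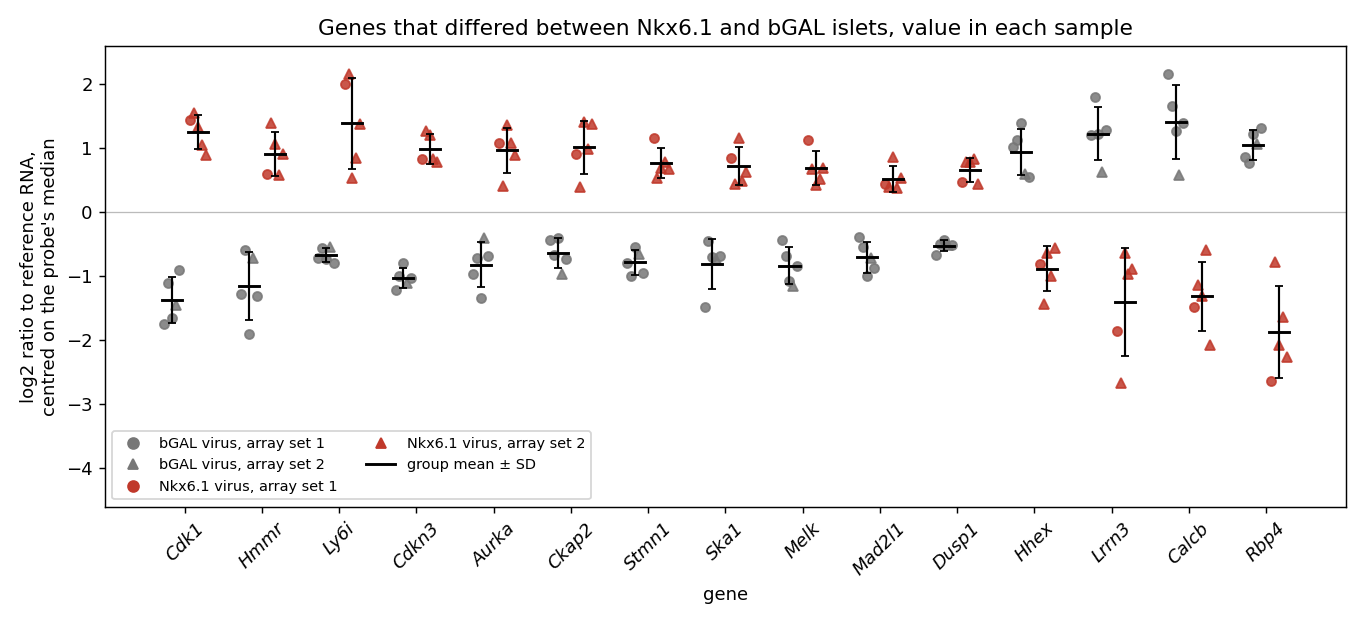
Points give the centred log2 ratio of each sample (vertical axis) for the 15 genes that changed (horizontal axis), grey for bGAL and red for Nkx6.1, circles for array set 1 and triangles for array set 2, with lines for the group mean and bars for the SD (n = 5). In each gene all 5 Nkx6.1 samples lie on one side of all 5 bGAL samples, above them in 11 genes and below them in 4.

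The 15 changed genes were found among 9974 tested genes with limma at an adjusted p threshold of 0.05, with 962 genes at an unadjusted p under 0.05. At the level of single probes, 15 of 18546 changed, 12 higher and 3 lower. They included 1 of 2 probes for Tacc3, a spindle gene, which was 1.59 higher on the log2 scale, whereas the mean of both Tacc3 probes differed by 0.19 (adjusted p = 0.77). Against 11 rises and 4 falls with the values as deposited, 23 genes rose and 4 fell with quantile normalisation between arrays, 333 rose and 425 fell with array weights, and 7 rose and 11 fell without bGAL replicate 4. With the replicate number as a block, limma called 0 genes and 0 probes (811 genes and 1413 probes at an unadjusted p under 0.05). With a term for the array set, Cdk1, Cdkn3 and Melk remained past the threshold and no probe did. Then 506 genes and 842 probes had an unadjusted p under 0.05, near the 1 in 20 that chance alone gives. The differences of the 15 genes with the term were between 0.86 and 1.19 times those without it, and their SE was a median of 1.27 times as large. The log2 difference of Cdk1 was 2.79 within array set 1 and 2.65 within array set 2, and that of Rbp4 was −3.68 and −2.76. The number of changed genes depended on single samples: 36 genes changed without Nkx6.1 replicate 2, 6 without bGAL replicate 1 or 5, 3 without bGAL replicate 3 or Nkx6.1 replicate 4, and 2 without bGAL replicate 2 or Nkx6.1 replicate 3 or 5.

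The next comparison concerned proliferation, through 3 lists of cell cycle genes. The G2/M and mitosis list rose as a group, with a median log2 difference of 1.12 and 33 of its 42 measured members higher with the Nkx6.1 virus (camera adjusted p = 2.2e-16, and adjusted p = 0.0050 with an estimated correlation). In this list 7 genes rose at the threshold over all genes, and 18 rose when adjusted over the list alone. Its mean per sample was 0.40 ± 0.33 with the Nkx6.1 virus and −0.61 ± 0.26 with the control virus (SD, n = 5). The median log2 difference of the list was 1.25 with a term for the array set, 1.42 within array set 1 and 1.25 within array set 2. The mean of the leukocyte markers moved the other way in the same samples, −0.36 ± 0.20 with the Nkx6.1 virus and 0.66 ± 0.64 with the control virus. For genes of DNA replication, the list mean per sample overlapped between groups, 0.073 ± 0.28 with the Nkx6.1 virus and −0.082 ± 0.33 with the control virus (SD, n = 5). Their log2 difference had a median of 0.50 and a mean of 0.15, with 14 of 24 members higher (camera adjusted p = 0.015). That call was lost with an estimated correlation (adjusted p = 0.18), with fry (adjusted p = 0.15) and without bGAL replicate 5 (adjusted p = 0.059) or Nkx6.1 replicate 1 (adjusted p = 0.16). None of the 24 passed over all genes, and 2 rose when adjusted over the list alone. The members with the smallest p were Mcm6 and Mcm7, subunits of the replicative helicase, with log2 differences of 1.12 and 0.82, the clamp loader gene Rfc3 with 0.99 and the flap endonuclease gene Fen1 with 0.55. Within array sets 1 and 2 the median of the DNA replication list was 0.63 and 0.45.

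Regulators of the G1/S transition did not pass as a list (median log2 difference 0.083, camera adjusted p = 0.17), and none of its 11 members passed. Its median was 0.75 within array set 1 and 0.13 within array set 2. Without Nkx6.1 replicate 2 the list passed, with a median of 0.44 and adjusted p = 0.0034 (adjusted p = 0.056 with an estimated correlation). The log2 difference was 1.91 for Cdc6, 1.32 for cyclin D1 (Ccnd1), −0.27 for cyclin D2 (Ccnd2), 0.60 for Cdk2 and 0.04 for Cdk4, none past the threshold. Cdk2 differed by 0.35 without bGAL replicate 2, and Cdc6 by 1.22 with the array set term. The sign turned with quantile normalisation for Ccnd2 and with the array set term for Cdk4. Within array sets 1 and 2 the difference was 0.17 and −0.57 for Ccnd2 and −0.23 and −0.078 for Cdk4. Cyclin A2 (Ccna2) had a log2 difference of 2.04 that did not pass (adjusted p = 0.22), with 4 of 5 Nkx6.1 samples above all bGAL samples, and passed without Nkx6.1 replicate 2 (2.42, adjusted p = 0.023). The cyclin-dependent kinase inhibitors were not shifted as a list of 5 (median −0.10, camera adjusted p = 0.78), and Cdkn1b, which encodes p27, had a log2 difference of 0.40 (adjusted p = 0.55).

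The third comparison concerned the function of the islets. None of the 3 lists of islet function genes was shifted. The 8 hormone genes had a median log2 difference of 0.061 (camera adjusted p = 0.67) and none passed. Insulin 1 and insulin 2 (Ins1 and Ins2) had log2 differences of 0.999 ± 0.627 and 0.85 ± 0.57 (limma estimate ± SE), amylin (Iapp) 0.69, and glucagon (Gcg) 0.15, whose sign turned with quantile normalisation. Somatostatin (Sst) had a log2 difference of −1.09 ± 0.68 (SE, adjusted p = 0.57). In 1 sample, Nkx6.1 replicate 2, the hormone genes stood far from the rest of the group, at 3.14 for Ins1 and 2.12 for Sst, while the other 4 Nkx6.1 samples lay between −0.53 and 0.83 for Ins1 and between −1.77 and −1.20 for Sst. Without that sample, Sst passed the threshold (log2 difference −1.81, adjusted p = 0.011), and the median of the hormone list was −0.38 (adjusted p = 0.058). The differences were then 0.40 for Ins1, 0.35 for Ins2, 0.13 for Iapp and −0.32 for Gcg. Within array sets 1 and 2 the median of the hormone list was −0.29 and 0.62, and the differences were −0.17 and 0.88 for Ins1, −0.41 and 0.87 for Ins2, −0.060 and 0.69 for Iapp and −0.85 and 0.55 for Gcg.

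Genes of glucose sensing and insulin secretion had a median log2 difference of 0.041 and a mean of −0.21, and 16 of 29 were higher (camera, direction up, adjusted p = 0.64). None passed over all genes and 1 rose when adjusted over the list alone. Vgf, which encodes a granule protein of neuroendocrine cells, had a log2 difference of 2.19 ± 0.48 (SE, adjusted p = 0.19), and all 5 Nkx6.1 samples lay above all bGAL samples. It passed without Nkx6.1 replicate 2 (1.70, adjusted p = 0.0090) and with quantile normalisation (2.34, adjusted p = 0.027). The glucose transporter gene Slc2a2 had a log2 difference of 0.65, the mitochondrial glycerol phosphate dehydrogenase gene Gpd2 one of −0.98 and Rab3a one of 0.77 (within 0.001 of 0 in array set 1, 0.59 in array set 2), none past the threshold. Islet transcription factors had a median log2 difference of −0.44, with 8 of 10 lower (camera adjusted p = 0.36). Among them Pax6 had a log2 difference of −2.97, Nkx2-2 one of −0.72 and Myt1 one of 4.93, none past the threshold, the last from values of 13.3 in 2 samples against the floor in most others. Pax6 differed by −3.77 within array set 1 and 0.15 within array set 2, Nkx2-2 by −0.91 and −0.0070, and Myt1 by 0 and 4.38. With the most variable probe per gene the difference was −9.58 for Pax6 and −1.37 for Nkx2-2, and Nkx2-2 differed by −0.35 without bGAL replicate 2. Pax6 differed by −0.77 without floored probes, and also without probes with a value above 8 in size. The median of this list was −0.12 within array set 1 and 0.11 within array set 2, and that of the glucose sensing list was 0 within array set 1 and 0.13 within array set 2.

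The probe for endogenous rat Nkx6-1 was not higher in the Nkx6.1 samples, with a log2 difference of −0.56 ± 0.29 (SE, limma adjusted p = 0.55, exact two-sided permutation p = 0.095, n = 5 per group). The virus carried the hamster gene, and whether the rat probe detects it is not given in the sources used here, so the probe does not check the labels. The difference was −0.084 within array set 1 and −0.29 within array set 2, and −0.34 without Nkx6.1 replicate 2. Nr4a1 and Nr4a3, nuclear receptor genes induced early after stimulation, had log2 differences of 0.82 and 0.90 that did not pass, and Nr4a3 of Nkx6.1 replicate 2 stood at −5.59 against 0.76 to 1.71 in the other 4 Nkx6.1 samples. The difference of Nr4a3 was 1.98 within array set 1 and −0.37 within array set 2.

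Of all 21 gene lists tested, 8 were shifted, 6 upward and 2 downward, and 4 were shifted with an estimated correlation. Interferon and antiviral genes rose as a list, with a median log2 difference of 0.52 and 12 of 17 members higher (camera on the 14 members with 10 values, adjusted p = 1.8e-05, and adjusted p = 0.0099 with an estimated correlation). The median was 1.14 over probes with 10 values and 0.17 with at least 2 values per group. None of them passed over all genes, and 7 rose when adjusted over the list alone. The immunoproteasome genes Psmb9 and Psmb8 had log2 differences of 1.66 and 1.02, Cxcl10, an interferon-induced chemokine, one of 1.33 and Oasl one of 1.52 (within 0.001 of 0 in array set 1, 1.64 in array set 2). The median of the list was 0.86 within array set 1 and 0.55 within array set 2. Immediate early genes rose as a list (median 0.31, 13 of 16 higher, camera adjusted p = 0.0012, and adjusted p = 0.038 with an estimated correlation), with Dusp1 past the threshold over all genes and 2 genes when adjusted over the list alone. Without Nkx6.1 replicate 2 the call at an estimated correlation was lost (camera adjusted p = 0.083). Fosl1 and Egr1, transcription factor genes of this list, had log2 differences of 0.76 and 0.58. The medians of this list within array sets 1 and 2 were 0.12 and 0.38. Genes of the p53 response and apoptosis had a median of 0.33 with 12 of 17 higher (camera adjusted p = 0.015), a call lost with an estimated correlation (adjusted p = 0.071) and without Nkx6.1 replicate 1 (adjusted p = 0.058). In this list 2 genes rose when adjusted over the list alone, and the log2 difference was 0.80 for Tp53inp1, 1.06 for Gadd45a, 1.94 for Gadd45b and 0.66 for Bax. The medians of this list were within 0.001 of 0 in array set 1 and 0.44 within array set 2, and 8 of the 17 genes had a floored probe.

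Markers of macrophages and other leukocytes fell as a list, with a median log2 difference of −0.78 and 15 of 16 lower (camera adjusted p = 0.0016, and adjusted p = 0.033 with an estimated correlation). No member passed, over all genes or over the list alone, with limma. The MHC class II gene RT1-Da had a log2 difference of −1.64, the complement gene C1qb −1.45, Cd53 −2.78 (−1.66 without Nkx6.1 replicate 2, −1.01 with array weights) and the macrophage receptor gene Adgre1 −0.83. The median of the list was −0.38 with a term for the array set, −0.47 within array set 1 and −0.38 within array set 2. Genes of cholesterol and fatty acid synthesis had a median of −0.43 with 17 of 21 lower (camera adjusted p = 0.0043), a call lost with an estimated correlation (adjusted p = 0.19) and with fry (adjusted p = 0.060). None passed over the list alone. Sqle and Idi1, enzymes of the sterol pathway, had log2 differences of −0.94 and −1.41, Fdps −0.61 and Lss −0.56 (0.0089 and −0.53 within array sets 1 and 2). With the array set term Sqle differed by −0.58, Idi1 by −0.76 and Lss by −0.26, and Fdps differed by −0.34 without bGAL replicate 5. The medians of this list within array sets 1 and 2 were −0.23 and −0.25. Acinar markers, which report digestive-enzyme cells of the exocrine pancreas, had a median of 0.25 with 13 of 17 higher (camera adjusted p = 0.025). That call was lost with an estimated correlation (adjusted p = 0.18), with fry (adjusted p = 0.15), with array weights (adjusted p = 0.24), with quantile normalisation (adjusted p = 0.060), and without bGAL replicate 4 (adjusted p = 0.056), Nkx6.1 replicate 1 (adjusted p = 0.051) or Nkx6.1 replicate 2 (adjusted p = 0.13), and 13 of the 17 genes had a floored probe. Its median was within 0.001 of 0 in array set 1 and 0.14 in array set 2. Ctrb1, Cpa1 and Ela2, digestive protease genes, had log2 differences of 0.77, 0.59 and 0.47 (−0.027 and 0.96 within array sets 1 and 2 for Ela2), and Reg3a one of −4.36, with values of 13.1 and 6.59 in bGAL replicates 1 and 2 (−2.03 without bGAL replicate 1).

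**Figure D3:**
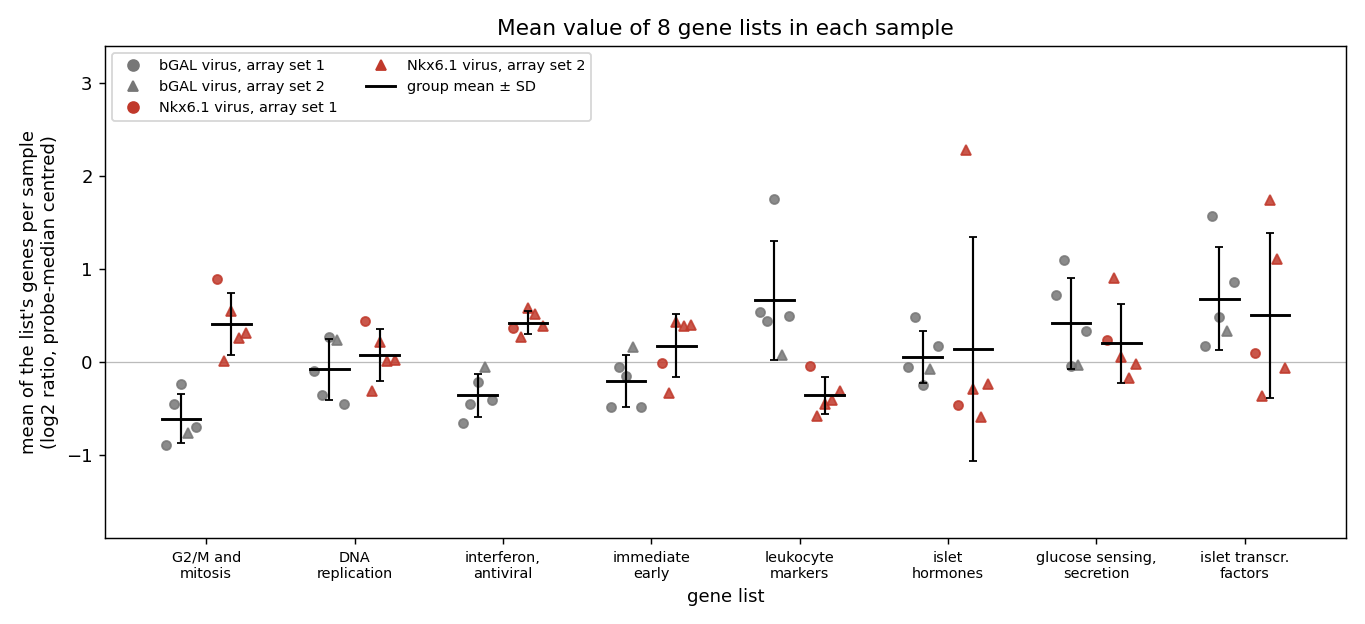
Points give the mean centred log2 ratio of a gene list in each sample (vertical axis) for 8 lists (horizontal axis), grey for bGAL and red for Nkx6.1, circles for array set 1 and triangles for array set 2, with lines for the group mean and bars for the SD (n = 5). The mitosis means lie higher in all 5 Nkx6.1 samples than in any bGAL sample, and Nkx6.1 replicate 2 stands at 2.28 for the islet hormones.

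The other lists were not shifted. The median log2 difference was 0.082 for inflammation and NF-κB genes (camera adjusted p = 0.095), a list that passed with a term for the array set (median 0.23, adjusted p = 0.0038), with quantile normalisation (0.23, adjusted p = 0.043), without floored probes (0.60) and without bGAL replicate 1 or 3 or Nkx6.1 replicate 2. With an estimated correlation it did not pass (camera adjusted p = 0.39, and 0.35 without Nkx6.1 replicate 2). The median log2 difference was 0.33 for duct markers (adjusted p = 0.25), −0.22 for stellate cell and fibroblast markers (adjusted p = 0.64), −0.067 for endothelial markers (mean −1.28, adjusted p = 0.93) and −0.16 for neuronal genes (mean −1.56, adjusted p = 0.93). It was −0.12 for ER stress genes (adjusted p = 0.67), −0.19 for glycolysis and hypoxia genes (adjusted p = 0.51) and −0.057 for oxidative phosphorylation genes, whose mean was 0.020 (camera, direction up, adjusted p = 0.67), a list that passed with array weights (median 0.15, adjusted p = 0.028). The list mean per sample reached 4.31 for endothelial markers in bGAL replicate 5 and 4.21 for neuronal genes in bGAL replicate 2. The sign of the difference turned under other settings for the endothelial, neuronal, oxidative phosphorylation, ER stress and kinase inhibitor lists.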

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

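The slope over narrower sets of probes, the term for the array set, its count over the 25 choices, and the comparison of the mitosis list and of the array-set split with the other splits were chosen only after the results were seen. The other tests of this part were chosen before their own results were seen. Those on Nkx6.1 replicate 2 and on the choices within the array sets were prompted by patterns already seen in the values. Single samples stood apart from the rest of their group in 30 of 180 comparisons within a group of 5, and 17 of the 30 concerned Nkx6.1 replicate 2. Chance alone gives about 1 in 20.

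In Nkx6.1 replicate 2, hormone genes and Vgf stood high, with a centred log2 ratio of 2.28 for the islet hormone list, 2.88 for Iapp, 2.12 for Sst and 3.30 for Vgf. So did single genes, with 1.74 for Mcm6, 1.36 for Mcm7, 1.31 for Rfc3, 1.45 for Psmb9, 2.12 for Cxcl10, 0.98 for Nr4a1 and 1.14 for Ela2, whereas the means of the DNA replication and interferon lists in this sample were −0.31 and 0.27. Standing low were Nr4a3 at −5.59, Ccnd2 at −2.18, the G1/S list at −1.52, the kinase inhibitor list at −1.30 and the cholesterol and fatty acid list at −0.67. The interquartile range of this array was 1.09.

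A mislabelled control sample is argued against. Over the 36 genes that changed without this sample, with the falls turned in sign, its mean was 0.94, against 0.96 ± 0.09 in the other 4 Nkx6.1 samples and −0.72 ± 0.09 in the 5 bGAL samples (SD). A wider ratio scale on this array cannot be told apart from other causes. The slope of its uncentred ratios on the mean of Nkx6.1 replicates 3 to 5 over all 7209 floored probes was 0.57, below the bound of 1.1 set against this explanation. But over all probes of this array 2611 sit at the floor, and those among the 7209 can pull that slope down. Without probes with a value above 8 in size the slope was 0.62, and over the 4889 of these that were also off the floor in all 5 arrays of set 2 it was 1.15, against 0.96 for bGAL replicate 4, which is between the bounds. No biological explanation was tested for this sample.

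In bGAL replicate 4, 5 genes stood apart, namely Ela2 at −0.56, Lss at −0.10, Myt1 at 2.37, Oasl at 0.17 and Rab3a at 0.25, and in Myt1, Oasl and Rab3a the other 4 bGAL samples shared the same floored value to within 0.001. The percent of probes without a value was 1.06 in bGAL replicate 4 and 31.4 in Nkx6.1 replicate 1, each far from the rest of its group. Cdk2 stood at −1.33 in bGAL replicate 2, Fdps at 1.55 in bGAL replicate 5, Ska1 at −1.48 in bGAL replicate 1, Fen1 at 0.020 in Nkx6.1 replicate 4 and Pax6 at 0.84 in Nkx6.1 replicate 3. The leukocyte marker list stood at 1.75 in bGAL replicate 3.

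Of 100 of the 126 possible splits of the 10 samples into 5 and 5, the real one included, 2 gave as many changed genes as the 15 found, with 258 in the highest other split, and 3 gave as many changed probes as the 15 found, with 618 in the highest other. The shares are under 0.05, which would make chance less likely for both counts if the 10 samples were exchangeable. But the split with 258 genes and 618 probes was the one by array set. That points to a structure of the samples larger than the group difference, so the samples cannot be taken as exchangeable. Chance is therefore not excluded by these shares. With a term for the array set, 3 genes and 0 probes passed. The differences of the 15 genes, picked in the fit without the term, kept their size, for example 1.79 ± 0.24 and 1.68 ± 0.30 for Aurka and −1.82 ± 0.24 and −1.66 ± 0.29 for Hhex without and with the term (SE), and their SE was a median of 1.27 times that without the term. Over all genes, 506 of 9974 had an unadjusted p under 0.05 with the term, against 962 without it. For probes these counts were 842 and 1651 of 18546. Chance alone gives about 1 in 20, so the shares with the term were near chance. For the number of shifted lists, 6 of 100 splits gave as many as the 8 found, with 9 in the highest other, so chance cannot be excluded for that number. In 1 of 100 splits, the real one, the p of the mitosis list was as small.

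The array sets were then kept in place, and only the 1 array of each set that stands in the other group was chosen anew, which gives 25 choices, the real one included, and 0.04 as the smallest share. In 1 of 25 as many genes changed as the 15 found, with 6 in the highest other. This is the smallest share that 25 choices can give, so it makes chance less likely but does not exclude it. In 2 of 25 as many probes changed as the 15 found, with 15 in the highest other, so chance cannot be excluded for that count. With a term for the array set, 5 of 25 gave as many genes as the 3 found, with 190 in the highest other, so chance cannot be excluded there either. In 1 of 25, the real one, the p of the mitosis list was as small, with a negative log10 p of 16.99 against 5.68 in the highest other. That share is also the smallest possible. The list had the smallest p of the 21 lists in the real groups, and the best list of each other choice was not compared. Chance is therefore not excluded for that list.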

How the results depend on the processing

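The array set term and leaving out floored or extreme probes were chosen after the data were seen. Of the 15 changed genes, 0 were called with the replicate number as a block, 3 with the array set term, 2 to 15 with 1 sample left out and 12 to 15 in the other settings. The mitosis list kept its direction and its call in all settings, with a median from 1.101 to 1.458. The number of changed genes and probes was 27 and 26 with quantile normalisation, 23 and 24 with trend and robust eBayes, 758 and 1389 with array weights (333 genes higher and 425 lower, 582 probes higher and 807 lower; Nkx6.1 replicate 2 had a weight of 0.10), 250 and 386 at an unadjusted p under 0.01, and 3 and 0 with the array set term, with which the differences of the 15 genes were 0.86 to 1.19 times as large and their SE a median of 1.27 times. All 15 genes were among the 758, and 13 were among the 27. Leaving out 1 sample gave 2 to 36 genes (36 without Nkx6.1 replicate 2, and 18 without bGAL replicate 4, 7 higher and 11 lower), 2 to 42 probes, 5 to 9 shifted lists (5 without Nkx6.1 replicate 1) and 1 to 3 shifted cell cycle lists. With an estimated correlation 4 lists were shifted and with fry 5, of which 1 was a cell cycle list in each, so the DNA replication list (median 0.50, 0.37 to 0.58 with 1 sample left out) lost its call in both. The G1/S list passed with array weights (0.72) and had a range of −0.043 to 0.44 with 1 sample left out. None of the islet function lists was shifted in any setting, but the direction of the hormone list turned with quantile normalisation (−0.15), array weights (−0.33), the array set term (−0.046) and 1 sample left out (−0.38 to 0.24), and that of the glucose sensing list with array weights (−0.27) and 1 sample left out (−0.22 to 0.22). The oxidative phosphorylation list passed with array weights (0.15). With the array set term the direction of its set test turned from up to down, while its median was below 0 without and with the term (−0.057 and −0.043). The inflammation list passed with quantile normalisation (0.23), the array set term (0.23), no floored probes (0.60) and 3 of the 10 samples left out in turn. It did not pass with an estimated correlation (camera adjusted p = 0.39). The median of the interferon list was 1.14 over probes with 10 values, 0.17 with at least 2 values per group and 0.90 with the most variable probe, and its set test stayed past the threshold. The acinar list lost its call with array weights (0.20) and fry (0.25), among others. Among lists that never passed, the direction of the set test turned for endothelial markers (quantile −0.015, most variable probe −0.022, array set term 0.23, no extreme probes 0.024, 1 sample left out −0.23 to −0.025), neuronal genes (fry −0.16, array set term 0.0011, no floored probes 0.51, no extreme probes 0.45, 1 sample left out −0.19 to 0.031), ER stress (array weights 0.046, 1 sample left out −0.22 to −0.014), kinase inhibitors (array set term 0.33, 1 sample left out −0.31 to 0.15) and stellate markers (no floored probes −0.21). The sign turned for Ccnd2 (quantile 0.0092, array weights 0.24, 1 sample left out −0.44 to 0.20), Gcg (quantile −0.053, array weights −0.21, array set term −0.15, 1 sample left out −0.32 to 0.38) and Cdk4 (array set term −0.15, 1 sample left out −0.057 to 0.21). The cause was not tested for these. With the replicate number as a block, limma called 0 genes and 0 probes, with 811 genes and 1413 probes at an unadjusted p under 0.05, and camera shifted 8 lists. Same-numbered samples had correlations of 0.15, 0.029, −0.019, 0.17 and −0.16 across 10164 probes, and 2 of the 5 bGAL samples correlated best with their own number. The same-numbered samples of replicates 2, 3 and 5 lay in different array sets. These correlations therefore cannot decide whether the numbers pair the samples. No signal over background was used here.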

Other observations

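The tests of the array sets, of leukocytes, of stellate cells, of exchanged labels, of Sst against other hormones and of the lists at an estimated correlation without Nkx6.1 replicate 2 were chosen only after the results were seen, and the list of further δ-cell genes was written before its values were seen.

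Without Nkx6.1 replicate 2, the sample that stood apart, 29 genes rose and 7 fell, and all 15 genes of the full comparison were among the 36. Of the mitosis list 12 genes passed, against 7 with all samples. Among the genes that joined those that rose were securin (Pttg1, log2 difference 2.39), Dlgap5 (1.97), the kinesin gene Kifc1 (1.18), Ccna2 (2.42), the replication genes Mcm6 (0.86) and Dscc1 (1.36) and the adhesion gene Icam1 (1.74). Somatostatin (Sst, −1.81) and the protease inhibitor gene Serpina1 (−1.68) joined those that fell. These genes were named after their values were seen. As lists, DNA replication (camera adjusted p = 0.0011), G1/S regulators (0.0034) and inflammation (0.025) passed without that sample, but none of the 3 did with an estimated correlation (0.10, 0.056 and 0.35), and the acinar list lost its call (0.13). Immediate early genes passed with an estimated correlation in all samples, but not without that sample (camera adjusted p = 0.083).

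Of the genes known from δ cells, the somatostatin-producing cells of the islet, 3 were picked because they were seen to be lower with the Nkx6.1 virus, and of these Hhex and Rbp4 passed the threshold and Sst did not (adjusted p = 0.57). The mean log2 difference of Sst, Hhex and Rbp4 was −1.95, and it was −2.02 with a term for the array set, −2.44 within set 1 and −1.61 within set 2, but with the term Sst (adjusted p = 0.99) and Hhex (0.29) were far from the threshold and Rbp4 stood at 0.060, each set holds 1 array of one of the groups, and the 3 genes were picked for their fall, so the array sets cannot be told apart as its cause. To examine a move of all hormone genes alike, Sst was taken relative to the mean of Ins1, Ins2, Iapp, Gcg and Ppy in the same sample. It was −1.21 ± 0.74 with the Nkx6.1 virus and 0.41 ± 0.45 with the control virus (SD, n = 5). The difference was −1.62 (exact two-sided permutation p = 0.0079, the smallest that 5 against 5 can give), lower in all 5 Nkx6.1 samples. But Sst was picked for its fall before this test was chosen, and the permutation ignores the array sets. A move of all hormone genes alike is therefore less likely but not excluded. Fewer δ cells, or a lower δ-cell programme, is a hypothesis that further δ-cell genes did not decide: 6 of 9 measured were lower, with a median log2 difference of −0.060 (exact sign test, two-sided, p = 0.51), from −1.15 for Bche to 0.94 for Prg4, and 5 of the 9 had floored probes. A direct effect of the virus gene on Sst, Hhex and Rbp4 in single cells was not tested.

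Mitosis genes were higher with the Nkx6.1 virus. The median log2 difference of the list was 1.25 with a term for the set and above 0 within each set. That speaks against the array sets as the whole cause. In each set, though, 1 of the groups has only 1 array. These values therefore rest on Nkx6.1 replicate 1 and bGAL replicate 4, and do not exclude the array sets. Dividing leukocytes are not excluded. The mean of their markers was lower with the Nkx6.1 virus (difference −1.02, pooled SD 0.47, exact two-sided permutation p = 0.0079), which does not show how many of them divided. The permutation test ignores the array sets, and the median of the leukocyte list was −0.78 without and −0.38 with a term for the set. Dividing stellate cells cannot be told apart: the mean of their markers differed by −0.48 (pooled SD 0.41, exact two-sided permutation p = 0.087), and the bGAL values ranged from −0.094 to 1.26. Exchanged labels of bGAL replicate 4 and Nkx6.1 replicate 1, which would make the array sets the groups, were not decided. The mitosis list mean was −0.77 in bGAL replicate 4, −4.70 SD from the other 4 arrays of its set, and 0.89 in Nkx6.1 replicate 1, 5.09 SD from the other 4 of its set. Each lay on the side of its own label and outside the 95% prediction interval of 3.56 SD. But the list was picked for its difference with the labels as given, so this is not independent evidence. A first test, of whether the differences within the 2 sets correlated more than for any other pair of 1 array from each set, also left this open: r was 0.11 across 6214 genes, which are not independent, the third highest of 25 pairs (highest 0.24). The explanation of the higher mitosis transcripts is therefore left open, and which islet cells held them was not tested.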
